A study of Rattus norvegicus with 17 samples.

How the data were processed

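Gene expression was measured in liver of 17 rats (Rattus norvegicus) on the Affymetrix Rat Genome 230 2.0 array, with 1 array per rat: 6 sham, 6 ligated saline and 5 ligated ghrelin. Per the labels, the operation was at week 7 and the liver was taken at week 9. Total RNA was extracted on spin columns, checked on a Bioanalyser, reverse transcribed with an oligo-dT primer carrying a T7 promoter, transcribed into biotin-labelled cRNA, hybridized, and stained with streptavidin-phycoerythrin. Arrays are named here by group and a running number within the group, in the order of deposit.

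The deposited values are intensity values per probe set that the authors made with GCRMA, as the submitters' processing notes state. The version of GCRMA and its settings are not given in the sources used here. The deposited intensity values were on the linear scale, with all values above 2, and they were converted to log2 without a pseudocount. No values were missing and every column mapped to 1 rat. The number of arrays limits the precision of all values.

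Of 31099 probe sets, 57 controls were left out of the tests. A probe set was kept when its intensity exceeded the median of all deposited values (15.5, or 3.95 on the log2 scale) on at least 5 arrays, the size of the smallest group. This kept 15964 of 31042 probe sets. In the platform annotation 20826 probe sets have 1 gene symbol, 436 have several and 9780 have none listed. The symbols of 20764 were matched by gene identifier to the RefSeq annotation of the rat assembly GRCr8, which changed 0 symbols. That annotation served for names and gene length alone. A gene was represented by its kept probe set with the highest mean over all 17 arrays, among probe sets with 1 symbol, giving 9735 genes.

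Group means were fitted with limma 3.58.1 in R 4.3.3 in a model of 3 group means without covariates. Moderated variances came from eBayes with default settings (14 residual and 2.54 prior degrees of freedom), and p values were adjusted by the Benjamini-Hochberg method over the kept probe sets. A probe set was called at an adjusted p under 0.05. The 3 comparisons were ligated saline minus sham, ligated ghrelin minus ligated saline, and ligated ghrelin minus sham, the last of which holds ligation and ghrelin together. No paired analysis was made, because the numbers in the titles are not shared between groups. The labels used give no batch or date. Changes are given as log2 change ± SE from limma. Where all arrays of a group lay below the filter level, the fold is given as a bound against that level.

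Before the data were examined, 35 gene lists, the rule for named genes, the tests, the filter and most alternatives were fixed. Of 690 list entries 611 matched a gene on the array, and 517 list genes were kept. Lists with fewer than 3 measured members were not tested, which left 32. List shifts were tested with camera, with a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated from the residuals, each adjusted over the lists of a comparison. The mean over a list's genes minus the sham mean was also computed per array and tested by an exact two-sided permutation test. Members were further counted with p values adjusted over the list alone.

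Named genes were the 6 largest increases and 6 largest decreases among called genes whose groups did not overlap, the 2 members with the lowest p of each list that passed camera or had at least 25% of its members called, and 22 genes, mostly of fibrosis, bile ducts, inflammation, bile acids and the growth hormone and ghrelin systems, fixed in advance. This named 92 genes for ligation and 47 for ghrelin. Exceptions chosen after their values were seen are list members making up a count of 5 or fewer, and the male-biased, female-biased and clock genes of the closing section.

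The score of the ligation response used genes with an adjusted p under 0.05 and a change of at least 1 log2 unit between all 11 ligated arrays and sham, so that the choice of genes did not use the ghrelin label. Each array's score is the mean over these genes of the value minus the sham mean, signed by the direction of the pooled change. Signs of the ligation and ghrelin changes were compared gene by gene, with the 6 ligated saline arrays shared, with these arrays divided 3 and 3 in 20 ordered ways, and in 100 simulations without a ghrelin effect. RNA integrity was read from the 3' and 5' probe sets of beta-actin and GAPDH on each array.

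The fit was tested on simulated data of the same size, with 67, 67 and 66 probe sets given changes of 0.5, 1 and 2 log2 units. For ligation it recovered 47.8%, 83.6% and 100% of these, with 6 false calls of 160. For ghrelin it recovered 40.3%, 85.1% and 97.0%, with 4 false calls of 152. The simulated errors were independent between probe sets and few probe sets were changed. These rates test the fit and need not hold for the real arrays, where probe sets vary together.

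The alternatives fixed in advance were no filter, a stricter filter (mean above 7.67 on the log2 scale), quantile normalization, equal array medians, an intensity trend with a robust prior, array weights, a fit of the 2 compared groups alone, a further limit of 1 log2 unit, a log odds (limma B) above 0, leaving out each array in turn, other limits for the score, the mean of all probe sets of a gene, and the estimated correlation. After the data were seen, a comparison over lists of the share of the ligation change left with ghrelin, the beta-actin value as a covariate, removal of a gene length trend and leave-one-out of the RNA integrity controls were added, together with 4 gene lists of male-biased, female-biased, clock output and antiphase clock genes. For each comparison 100 of the 462 possible divisions of the arrays were drawn with seed 1, the real one included. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.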

Results

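Liver RNA from 17 rats was measured, with 1 oligonucleotide array per rat. Bile duct ligation blocks bile flow and is a standard way to produce cholestatic liver injury and fibrosis in the rat. Ghrelin is a peptide hormone, made mainly in the stomach, that acts through the growth hormone secretagogue receptor. The 6 sham rats had an abdominal incision and received saline, the 6 ligated saline rats had the bile duct ligated and received saline, and the 5 ligated ghrelin rats had the same ligation and received ghrelin at 10 µg/kg/day, all by osmotic minipump under the skin. The operation was at week 7 and the liver was taken at week 9, 2 weeks later. Ghrelin was not given to sham rats in the groups analysed here, so its effect without ligation was not measured.

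Per array, the median intensity over all probe sets lay between 14.2 and 14.7 in the sham group and between 15.4 and 17.6 in the 11 ligated arrays. Within groups, the correlation between arrays across probe sets, which are not independent replicates, ran from 0.965 to 0.985, and no 2 arrays held identical values. The leading principal component carried 69.1% of the variance, with the sham arrays between -88.95 and -78.57 and the ligated arrays between 19.04 and 80.06. The 3' minus 5' log2 value of the beta-actin control probe sets, a measure of RNA integrity, was 2.09 ± 0.167 (SD, n = 6) in sham, 1.94 ± 0.11 (n = 6) in ligated saline and 2.11 ± 0.302 (n = 5) in ligated ghrelin rats. Neither difference passed an exact two-sided permutation test (p = 0.0823 for ligation and p = 0.229 for ghrelin). For GAPDH the ligation difference was 0.02 (exact permutation p = 0.747) and the ghrelin difference 0.15 (exact permutation p = 0.0541, adjusted p = 0.165 over the 4 tests). Leaving out sham 6 gave an actin difference of -0.20 for ligation (exact permutation p = 0.00866), and leaving out ligated saline 3, ligated ghrelin 4 or ligated ghrelin 5 brought the GAPDH difference for ghrelin to p = 0.0476, p = 0.0429 and p = 0.0286 in the same test. The ligated ghrelin 3 array had the highest values of both controls, 2.62 for actin and 0.62 for GAPDH.

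The comparison of ligated saline with sham rats asked what ligation did to hepatic gene expression. After 2 weeks the livers held far more mRNA of collagens, bile duct cell keratins, inflammatory chemokines and mitotic genes, and less mRNA of enzymes of hepatocyte metabolism. Col1a1, a chain of fibrillar type I collagen, was 24.9 times its sham level and rose by 4.64 ± 0.289 (log2 change ± SE, n = 6 and 6), and the duct keratin Krt19 rose by 5.03 ± 0.493. Cyp2c11, a male-specific cytochrome P450 of rat liver, fell by 7.77 ± 0.845 on the log2 scale. Each of these genes moved the same way in 6 of 6 ligated rats and its groups did not overlap.

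In total, 9823 of 15964 probe sets passed limma at an adjusted p under 0.05, of which 5468 were higher and 4355 lower. The share of higher calls was 55.7% on the deposited values, 42.0% after quantile normalization and 39.0% with array medians set equal. These scalings moved the median change of all kept probe sets from 0.04 to -0.11 and -0.15, and without a filter 27.1% of 22230 calls were higher, so the balance of higher and lower calls depends on the scaling and the filter. By gene, 6301 of 9735 genes were called (3653 higher and 2648 lower), and 4285 of these had groups that did not overlap. Whatever their p, 4329 of the 9735 genes had groups without overlap, where chance gives 0.216% of genes. The changes were at least 1 log2 unit for 3338 probe sets. The 89 of the 92 genes named for this comparison that passed kept their direction and call under every alternative run on them, both scalings included. Members of a list named because few of them rose, fell or did not pass were chosen after their values were seen.

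The largest increases among genes with non-overlapping groups were those of Tsx, Cxcl6, Cd24, Msln, Loxl1 and Lcn2. Tsx rose by 9.14 ± 0.121 (adjusted p = 2.91e-18) and was at least 184-fold higher, since all its sham arrays lay below the filter level of 3.95. The neutrophil-attracting chemokine Cxcl6 rose by 7.07 ± 0.342 (adjusted p = 1.4e-10, at least 44-fold). Cd24, a surface protein of bile duct epithelium, rose by 7.01 ± 0.329, mesothelin (Msln) by 6.94 ± 0.402, the elastin cross-linking enzyme Loxl1 by 6.89 ± 0.297 and the acute phase protein lipocalin 2 (Lcn2) by 6.70 ± 0.902. The largest decreases were those of Stac3, Obp3, Car3, Cyp2c11, Dhrs7l1 and Inmt. Stac3 fell by 9.67 ± 0.171 (adjusted p = 1.93e-16) and was at least 352-fold lower, and Inmt, a methyltransferase, was at least 37.2-fold lower (log2 change -7.17 ± 0.468). The odorant-binding protein gene Obp3 changed by -9.33 ± 0.556, carbonic anhydrase 3 (Car3) by -9.11 ± 0.624 and Dhrs7l1 by -7.44 ± 0.588. The sham means of Msln (2.96) and Loxl1 (3.22) and the ligated saline mean of Dhrs7l1 (3.73) lie below the filter level as well, with some arrays above it, so the size of these changes and their order are approximate. The same holds for Krt7 and Abcc3 below, with sham means of 3.62 and 3.85.

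Genes of the scar matrix rose together. Of 27 measured genes of the fibrillar and basement membrane matrix, 26 rose, also when adjusted over the list alone, and 0 fell. The list mean was 3.10 ± 0.53 (SD over the 6 ligated saline arrays) above sham by camera (adjusted p = 1.12e-09, and adjusted p = 0.241 with an estimated correlation). Type III collagen (Col3a1) rose by 2.50 ± 0.138 and Col1a2 by 3.81 ± 0.252 (adjusted p = 5.47e-10 and 3.65e-09). The exception was fibronectin (Fn1), at 0.01 ± 0.072. It was at -0.182 with array medians set equal (adjusted p = 0.0357), a scaling that moves every probe set by -0.189, so this is not particular to Fn1. Among 16 stellate cell and myofibroblast markers, 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.26e-05, and adjusted p = 0.241 with an estimated correlation). Smooth muscle actin (Acta2), which marks activated stellate cells, rose by 2.64 ± 0.276, vimentin (Vim) by 3.54 ± 0.197 and Rgs5 by 3.09 ± 0.151. The member that fell was Lrat (-0.62 ± 0.178, adjusted p = 0.00673, lower in 5 of 6 rats), an enzyme with which quiescent stellate cells store vitamin A.

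Matrix proteases and their inhibitors rose as well, with 10 of 11 measured genes higher and 0 lower, and the same 10 adjusted over the list alone (camera adjusted p = 5.07e-05, and adjusted p = 0.241 with an estimated correlation). The gelatinase Mmp2 rose by 3.95 ± 0.241, and the inhibitors Timp1 and Timp2 by 3.37 ± 0.294 and 1.73 ± 0.105. Adamts1 did not pass (0.14 ± 0.137). In the TGF-beta pathway, 12 of 17 genes rose, 1 fell and 4 were not called, adjusted over the list alone too (camera adjusted p = 0.00136, and adjusted p = 0.292 with an estimated correlation). The ligands Tgfb3 and Tgfb1 rose by 4.30 ± 0.318 (at least 9.65-fold, with all sham arrays below the filter level) and 1.12 ± 0.184, and the latent TGF-beta binding protein Ltbp1 by 3.12 ± 0.261. Tgfbi fell by 0.52 ± 0.106 on the log2 scale (adjusted p = 0.000498), and Inhba, Smad2, Smad6 and Smad7 were not called. Smad6 had a value of 0.14 on the deposited scale and -0.24 after quantile normalization (adjusted p = 0.0123).

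Cholangiocyte markers, the genes of bile duct epithelium, had the largest list mean, 3.87 ± 0.586 above sham. Of 14 measured, 12 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 7.62e-06, and adjusted p = 0.241 with an estimated correlation). The secretin receptor (Sctr) rose by 6.49 ± 0.292 and the chloride channel Cftr by 5.69 ± 0.244, with all sham arrays below the filter level (at least 40.3-fold and 22.3-fold). Osteopontin (Spp1) rose by 5.53 ± 0.44 and Krt7 by 3.05 ± 0.343. The members that did not pass were Slc10a2 (1.08 ± 0.77) and Slc4a2 (0.01 ± 0.156).

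**Figure D1:**
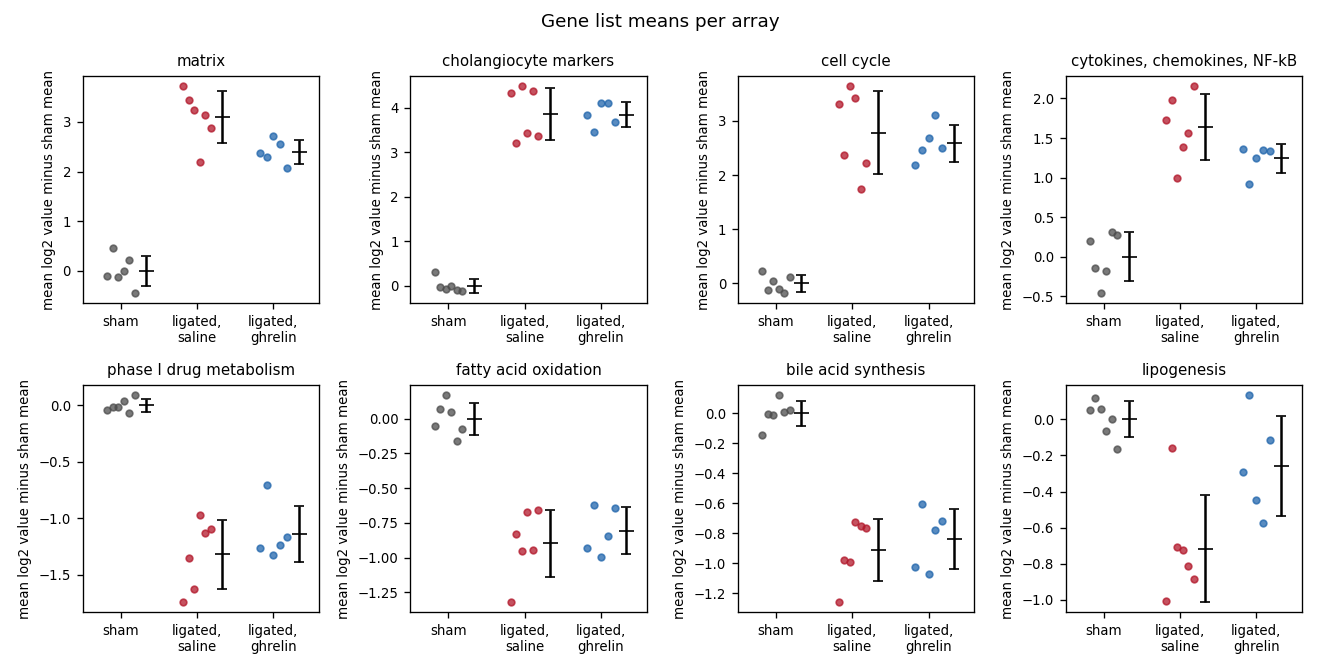
Mean log2 value of 8 gene lists on each of the 17 arrays, minus the sham mean, on the vertical axis, for sham, ligated saline and ligated ghrelin rats; points are arrays and bars the group mean ± SD. The matrix list lies 3.10 above sham with saline and 2.40 above sham with ghrelin, while the cholangiocyte list lies at 3.87 and 3.84.

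Inflammatory and immune cell genes were mostly higher. Of 24 cytokines, chemokines and NF-kB targets, 16 rose, 2 fell and 6 were not called, adjusted over the list alone too (camera adjusted p = 0.00136, and adjusted p = 0.292 with an estimated correlation). The monocyte chemokine Ccl2 rose by 4.14 ± 0.293, Ccl20 by 5.35 ± 0.286 (at least 15.4-fold, with all sham arrays below the filter level) and Nfkb2 by 2.87 ± 0.184, while Cxcl11 (-1.27 ± 0.191) and Cxcl12 (-0.56 ± 0.149) fell. All 6 measured neutrophil markers rose, with S100a8 at 3.51 ± 0.29 and S100a9 at 3.27 ± 0.333 (list camera adjusted p = 0.00859, adjusted p = 0.0679 without a filter, and adjusted p = 0.292 with an estimated correlation). Of 17 macrophage and Kupffer cell markers, 15 rose, or 16 adjusted over the list alone, which adds Mrc1 (0.26 ± 0.116), and Cd14 fell by 0.515 (camera adjusted p = 0.000294, and adjusted p = 0.323 with an estimated correlation). The complement genes C1qb and C1qa rose by 1.51 ± 0.157 and 1.26 ± 0.144. Of 8 MHC class II antigen presentation genes, 7 rose, among them RT1-DMa at 2.74 ± 0.29, and RT1-Bb was not called (camera adjusted p = 0.014, and adjusted p = 0.407 with an estimated correlation).

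Lymphocyte markers as a list did not pass (camera adjusted p = 0.469). Of the 5 measured, Ptprc (1.60 ± 0.195), Cd4 (1.10 ± 0.29) and Lck (1.34 ± 0.364) rose, perforin (Prf1) fell by 1.40 on the log2 scale and Cd3e was not called. Interferon response genes did not shift as a list either (camera adjusted p = 0.851), with 6 of 18 higher, among them Irf1 at 1.56 ± 0.213 and Psmb9 at 1.14 ± 0.148, and 2 lower, Stat2 (-0.72 ± 0.121) and Rsad2 (-1.35 ± 0.407). Endothelial markers went both ways (6 of 14 rose and 1 fell, camera adjusted p = 0.344), with Ramp2 at 1.21 ± 0.148 and the VEGF receptor Kdr at -0.82 ± 0.123. Acute phase genes did not shift as a list by camera (adjusted p = 0.357), although their list mean was 0.51 above sham (exact permutation adjusted p = 0.00577). Of 19, 8 were higher over all probe sets, 5 adjusted over the list alone (without Hp, Hpx and Serpina3n), and 2 lower. The lipopolysaccharide-binding protein gene Lbp rose by 2.15 ± 0.244, and the interleukin-6 receptor (Il6r, -1.52 ± 0.192) and Crp (-0.44 ± 0.139) fell.

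Cell division genes rose almost without exception. Of 31 measured cell cycle genes, 30 rose, also adjusted over the list alone, and Ccne1 (-0.15 ± 0.167) was not called but fell after quantile normalization (-0.457, adjusted p = 0.0177) (camera adjusted p = 3.41e-09, and adjusted p = 0.292 with an estimated correlation). The proliferation marker Mki67 rose by 4.54 ± 0.304 and Ube2c by 4.31 ± 0.324, or at least 9.83-fold, since its sham arrays lay below the filter level. Apoptosis regulators followed in part, with 13 of 22 higher and 1 lower (camera adjusted p = 0.013, adjusted p = 0.13 with the stricter filter, and adjusted p = 0.241 with an estimated correlation). The TWEAK receptor Tnfrsf12a rose by 4.68 ± 0.325 and Birc3, an inhibitor of apoptosis, by 3.54 ± 0.269, while Xiap, another inhibitor, fell by 0.841 on the log2 scale. Of 13 immediate early genes, 9 rose, such as Klf6 (2.598 ± 0.14) and Nr4a1 (2.49 ± 0.239, at least 2.73-fold with all sham arrays below the filter level), 1 fell, Dusp1 (-1.26 ± 0.362), and Ier2, Ier3 and Zfp36 were not called (camera adjusted p = 0.0107, adjusted p = 0.13 with the stricter filter, and adjusted p = 0.241 with an estimated correlation).

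Hepatocyte genes of lipid, sugar, nitrogen and drug metabolism fell, in the same livers in which bile duct, stellate and immune cell markers rose. Of 21 fatty acid oxidation and ketogenesis genes, 20 fell, or 21 adjusted over the list alone, which adds Ehhadh, by a list mean of -0.90 ± 0.242 (camera adjusted p = 3.67e-08, and adjusted p = 0.241 with an estimated correlation). The ketone body enzyme Bdh1 fell by 1.84 and the oxidation enzyme Hadh by 1.19 on the log2 scale. Of 26 phase I drug metabolism genes, 19 fell (20 adjusted over the list alone, which adds Cyp4a3), with Cyp4f4 at -1.70 ± 0.149 and Cyp4f1 at -1.19 ± 0.106, and Cyp2c22 rose by 0.43 ± 0.0694 (camera adjusted p = 7.62e-06, and adjusted p = 0.241 with an estimated correlation). Of 26 urea cycle and amino acid catabolism genes, 18 fell and 0 rose, among them Otc (-1.37 ± 0.189) and Hal (-3.81 ± 0.361) (camera adjusted p = 5.07e-05, and adjusted p = 0.323 with an estimated correlation). Glucose metabolism genes fell in 8 of 11 cases, led by Slc37a4 (-1.94 ± 0.117) and fructokinase (Khk, -1.72 ± 0.128), while Ppargc1a rose by 0.85 ± 0.301 (list camera adjusted p = 0.000949, and adjusted p = 0.283 with an estimated correlation). The Ppargc1a call was lost under both scalings and without ligated saline 2 or 3 (highest adjusted p 0.0807).

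Lipid synthesis genes were lower too. In the lipogenesis list 11 of 16 genes fell, with Acly at -1.53 ± 0.171 and Elovl5 at -1.35 ± 0.116, and the fatty acid transporter Cd36 rose by 1.86 ± 0.328 (list camera adjusted p = 0.00111, and adjusted p = 0.292 with an estimated correlation). Fasn, Acaca, Acacb and Gpam were not called. Of 17 cholesterol synthesis and uptake genes, 11 fell and 0 rose, such as Nsdhl (-1.01 ± 0.152) and Fdft1 (-1.20 ± 0.191) (camera adjusted p = 0.00136, and adjusted p = 0.423 with an estimated correlation). Of 23 hepatocyte secreted proteins and coagulation factors, 14 fell and 0 rose, with a list mean of -0.27 ± 0.126 (camera adjusted p = 0.00136, adjusted p = 0.078 after quantile normalization, and adjusted p = 0.323 with an estimated correlation). F12 fell by 0.632 and Rbp4 by 0.444 on the log2 scale. Albumin (Alb) was at -0.05 ± 0.05, and at -0.24 with array medians set equal (adjusted p = 0.00127). Its values of 15.79 to 15.92 lie at or near the maximum of every array, where a change can be compressed, so neither value is read as a stable or a lower level.

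Of 16 bile acid synthesis genes, 12 fell (13 adjusted over the list alone, which adds Cyp27a1) and 0 rose (camera adjusted p = 9.91e-05, and adjusted p = 0.241 with an estimated correlation). The sterol 12-alpha-hydroxylase Cyp8b1 fell by 3.81 ± 0.582 on the log2 scale, Amacr by 2.16 and Hsd3b7 by 1.38, while Cyp7a1, the rate-limiting enzyme, was at 0.30 ± 0.233 (adjusted p = 0.272, higher in 5 of 6 rats), and Nr0b2 and Nr5a2 were not called either. Among 15 hepatobiliary transporters, 10 fell, 2 rose and 3 were not called (camera adjusted p = 0.00581, and adjusted p = 0.241 with an estimated correlation). The basolateral bile acid importer Slc10a1 fell by 1.29 and the canalicular exporter Abcc2 by 2.42 on the log2 scale, whereas the basolateral exporter Abcc3 rose by 4.54 ± 0.186 and the phospholipid floppase Abcb4 by 1.24 ± 0.206. The bile salt export pump Abcb11 was at -0.30 ± 0.16 (adjusted p = 0.119) and passed with array medians set equal (-0.49, adjusted p = 0.017) and without ligated saline 2 (-0.40, adjusted p = 0.0263) or 4 (-0.38, adjusted p = 0.0494). Atp8b1 and Abcc4 were not called, although Atp8b1 passed adjusted over the list alone.

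**Figure D2:**
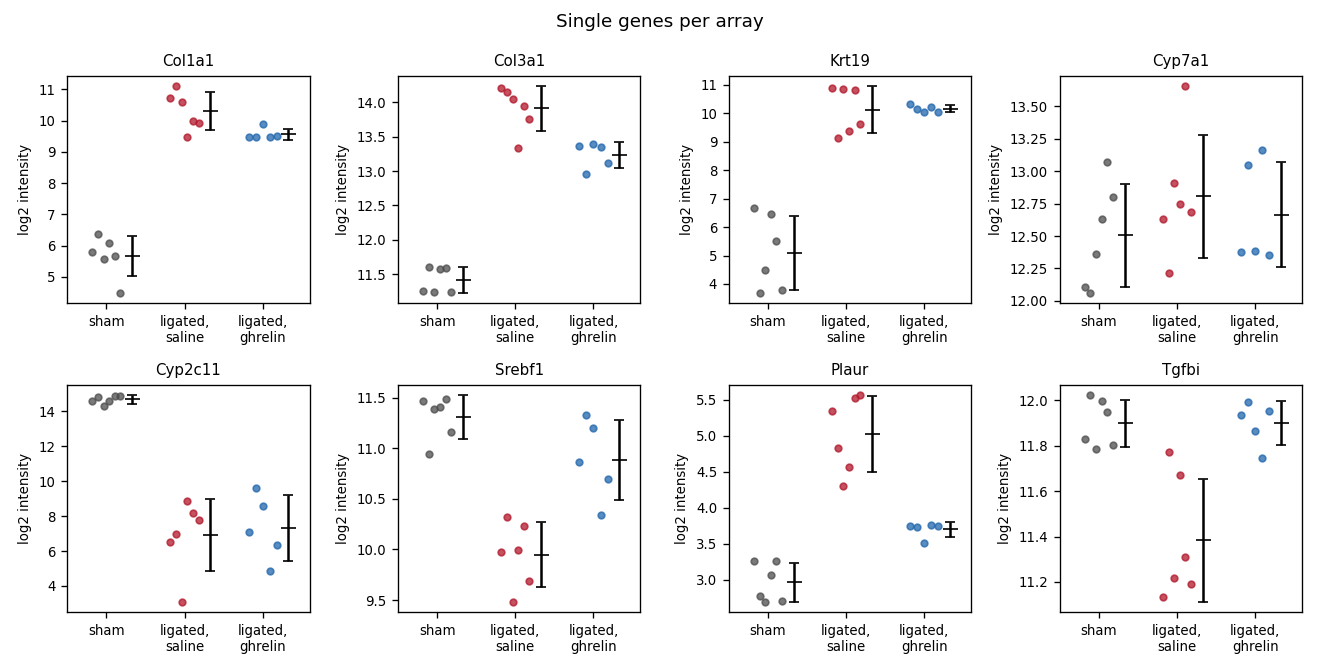
Log2 intensity of 8 genes on each of the 17 arrays, on the vertical axis, for sham, ligated saline and ligated ghrelin rats; points are arrays and bars the group mean ± SD. Col1a1 has means of 5.67, 10.30 and 9.56 in the 3 groups and Plaur of 2.96, 5.02 and 3.70.

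The remaining lists held members moving both ways. For antioxidant and glutathione genes, 6 of 25 rose and 14 fell, the mean change was 0.12, the median -0.20 and camera gave a decrease that did not pass (adjusted p = 0.0793). Gpx2 rose by 6.29 ± 0.3 (at least 27.1-fold, with all sham arrays below the filter level) and heme oxygenase 1 (Hmox1) by 1.40 ± 0.244, and Gclc, a subunit of the enzyme that limits glutathione synthesis, fell by 1.54, while Mt2A, Prdx6, Nqo1, Gsta3 and Srxn1 were not called. In the growth hormone and IGF axis, 6 of 18 rose and 7 fell, with a mean of 0.18, a median of -0.20 and a decrease by camera that did not pass (adjusted p = 0.534). Igfbp7 rose by 2.43 ± 0.163, and the growth hormone receptor (Ghr, -1.57 ± 0.148), Igfals (-1.79 ± 0.139) and Igf1 (-0.43 ± 0.0922) fell, while Igfbp3, Prlr, Socs2, Cish and Stat5a were not called. Prlr stood at 0.03 ± 0.965 and fell by 1.105 without sham 5 (adjusted p = 0.0338), and Stat5a fell by 0.331 after quantile normalization (adjusted p = 0.00658). For ER stress, 3 of 19 rose, Atf3 (2.11 ± 0.209), Asns (1.95 ± 0.469) and Hsp90b1 (0.26 ± 0.0985), and 9 fell, among them Herpud1 (-1.41 ± 0.174), with no shift of the list (camera adjusted p = 0.126). The Hsp90b1 call was lost with array medians set equal (0.07) and without sham 1, 3 or 6 or ligated saline 1, 3 or 6 (highest adjusted p 0.552).

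Markers of other tissues were few. Erythroid markers were represented by Alas2 (-2.995 ± 0.461) and Hbb (-1.17 ± 0.204), which fell, and Ahsp, which was not called (camera adjusted p = 0.0693). Of 4 adipocyte markers Fabp4 rose by 4.55 ± 0.377, Cidec fell by 0.442 with overlapping groups, and Cfd and Lipe were not called (camera adjusted p = 0.851). Of 3 intestinal epithelium markers, Vil1 rose by 2.28 ± 0.365 (at least 2.42-fold, with all sham arrays below the filter level), Apoa4 fell by 2.85 and Fabp2 was not called, with a list mean of -0.04, a median of 0.44 and camera pointing down without passing (adjusted p = 0.851). With a sham mean of 14.01, Apoa4 was abundant in the sham livers themselves, so this list is not read as a sign of intestinal tissue. Of 9 housekeeping genes, 6 rose, such as Ywhaz (0.92 ± 0.102) and Hprt1 (0.90 ± 0.0986), Sdha fell by 0.663, and Pgk1 and Tbp were not called (camera adjusted p = 0.126). The housekeeping list passed without a filter, with a stricter filter and after quantile normalization (lowest adjusted p = 0.0143), the acute phase list without a filter, and the erythroid list without a filter and without ligated saline 5 or 6 (lowest adjusted p = 0.0402). The pancreatic acinar, skeletal muscle and ghrelin system lists had fewer than 3 measured members and were not tested. Tnf, ghrelin (Ghrl) and its receptor (Ghsr) did not pass the filter, with highest values of 5.13, 1.90 and 2.30.

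Of 32 lists tested, 21 shifted with ligation by camera with its preset correlation (12 up and 9 down), and 0 did with an estimated correlation, where the lowest adjusted p was 0.241 and 4 lists had an unadjusted p under 0.05. An exact permutation test of each list's mean per array, which asks only whether the list's own mean differed between groups, passed for 26 of the 32 lists after adjustment (lowest adjusted p = 0.00314), including all 21. Beyond those 21, the means of the adipocyte (1.08), endothelial (0.37), housekeeping (0.32) and erythroid (-1.55) lists differed from sham in this test (adjusted p = 0.00314 each). So did the acute phase list (0.51, adjusted p = 0.00577). Of 100 splits of the 12 arrays, 8 shifted at least 21 lists, so chance was not excluded for the number of lists by camera. The other splits shifted a median of 13 lists, so that count separates the groups poorly, while 1 split, the real division, called 9823 probe sets. Splits with sham and ligated arrays in unequal shares keep part of the ligation effect, which can raise their counts.

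The comparison of ligated ghrelin with ligated saline rats asked what ghrelin changed in livers with the same ligation. Livers of ghrelin-treated rats held less mRNA of the urokinase receptor Plaur, of Col3a1 and of the prostaglandin synthase Ptgs2, and more of Srebf1, the regulator of lipogenic genes. Plaur fell by 1.32 ± 0.206 on the log2 scale (adjusted p = 0.0127, n = 5 and 6) and was at least 2.1-fold lower, with all 5 ghrelin arrays below the filter level. Col3a1 fell by 0.68 ± 0.145 (adjusted p = 0.0342) and Srebf1 rose by 0.94 ± 0.18 (adjusted p = 0.024), each in 5 of 5 rats. In a fit of the 2 compared groups alone Plaur passed, and Col3a1 (adjusted p = 0.0661), Srebf1 (adjusted p = 0.0588) and Ptgs2 (adjusted p = 0.088) did not. The Col3a1 difference was small beside that of ligation. Ghrelin means of Plaur (3.70), Srebf1 (10.89) and Ptgs2 (3.88) lay nearer to sham (2.963, 11.31 and 3.275) than to saline (5.02, 9.95 and 4.95). The sham and ghrelin means of Plaur and Ptgs2 lie below the filter level, so their distances are approximate. Of 14 cholangiocyte markers 0 passed, with Krt19 at 0.03 ± 0.517 (adjusted p = 0.976) and Spp1 at -1.25 ± 0.462 (adjusted p = 0.136, lower in 5 of 5 rats).

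Of 15964 probe sets, 355 passed limma, 210 higher and 145 lower, against 3393 with an unadjusted p under 0.05. The share of higher calls was 59.2% on the deposited values, 67.3% after quantile normalization and 80.4% with array medians set equal. By gene, 228 were called (171 higher and 57 lower), 158 of them without overlap between the groups. Whatever their p, 441 of all 9735 genes had groups without overlap, where chance gives 0.433% of genes. Of the 35 probe sets with a change of at least 1 log2 unit, 9 were higher and 26 lower, the reverse of the balance among all calls. The count of 355 moved with single arrays. It was 51, 55, 75 and 141 without ligated saline 1, 3, 5 and 6, and 97, 35, 122 and 52 without ligated ghrelin 1, 2, 3 and 5, but 653 without ligated saline 4 and 599 without ligated ghrelin 4. It was 196, 215, 198 and 221 without sham 1, 2, 5 and 6. With the actin 3' minus 5' value as a covariate, added after the data were seen, 44 probe sets passed.

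The largest increases without overlap were in Plekhb1 (1.22 ± 0.257, adjusted p = 0.0324), Pced1b (1.14 ± 0.209, adjusted p = 0.0193), Fance (0.999 ± 0.146, adjusted p = 0.0104), Sec31a (0.99 ± 0.188, adjusted p = 0.0217), Itga5 (0.94 ± 0.134, adjusted p = 0.0101) and Srebf1. Fance belongs to the Fanconi anaemia DNA repair complex, Sec31a to the coat of vesicles leaving the endoplasmic reticulum, and Itga5 is the alpha chain of the fibronectin receptor. The largest decreases were in Olr1, a scavenger receptor for oxidized LDL (-1.52 ± 0.382, adjusted p = 0.0492), Plaur, Arl11 (-1.17 ± 0.239, adjusted p = 0.0299), Far1 (-1.05 ± 0.197, adjusted p = 0.0211), Abcc5 (-1.04 ± 0.175, adjusted p = 0.0127) and Afap1l2 (-0.91 ± 0.214, adjusted p = 0.0414). All of them lay beyond the ligated saline mean in 5 of 5 rats. Relative to sham, Olr1, Plaur, Arl11, Far1, Abcc5 and Afap1l2 had higher means with saline (7.71, 5.02, 7.05, 6.52, 6.78 and 5.34) than in sham (3.67, 2.96, 4.46, 4.96, 5.37 and 3.19), with the ghrelin means between them (6.19, 3.70, 5.88, 5.47, 5.73 and 4.42, Plaur being below the filter level in both sham and ghrelin rats). Plekhb1 (9.59) and Srebf1 (10.89) had ghrelin means between saline (8.37 and 9.95) and sham (10.03 and 11.31). The ghrelin means of Pced1b (6.51), Fance (5.06), Sec31a (7.78) and Itga5 (6.82) lay above sham (5.97, 4.16, 7.27 and 6.11), with the saline means below it (5.38, 4.06, 6.79 and 5.88). Pced1b, Fance, Itga5, Plaur and Abcc5 passed under each of the 24 alternatives run on them. The stricter filter dropped these genes, and the actin covariate and the length trend were not run on single genes. The saline mean of Fance (4.06) also lies close to the filter level. The other 11 of the 16 named genes that passed lost the call under at least 1. In the fit of the 2 compared groups alone 10 of the 16 lost it, without a filter 7 of 16, and with single arrays left out 69 of 272 results, and Olr1 kept it in 8 of 24 alternatives.

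Matrix, stellate cell and protease lists were lower with ghrelin by camera with its preset correlation and did not pass the other tests. Of 27 matrix genes, 1 fell over all probe sets, Col3a1, and 15 fell adjusted over the list alone, and 0 rose. The list mean was 2.40 ± 0.244 above sham with ghrelin and 3.10 ± 0.53 with saline, a difference of -0.70 (camera adjusted p = 1.59e-09, adjusted p = 0.583 with an estimated correlation, and exact permutation p = 0.0325, adjusted p = 0.173). Col1a1 (-0.74 ± 0.303, adjusted p = 0.173), Col1a2 (-0.87 ± 0.265, adjusted p = 0.0814) and Col6a3 (-1.08 ± 0.282, adjusted p = 0.0528) did not pass, and each had a lower value than the saline mean in 5 of 5 rats. The other probe set of Col6a3 passed (-1.56 ± 0.251, adjusted p = 0.0127), and so did the mean of both (-1.32, adjusted p = 0.0188), the brighter probe set with a stricter filter, an intensity trend, both scalings and without ligated saline 4 or ligated ghrelin 4. Without ligated saline 4, Col1a2 passed too (-1.05, adjusted p = 0.0269). Stellate cell and myofibroblast markers had 1 of 16 lower, Rgs5 (-0.70 ± 0.158, adjusted p = 0.0389), and 4 adjusted over the list alone, which adds Reln, Pdgfra and Hgf (list difference -0.48, camera adjusted p = 3.78e-05, adjusted p = 0.583 with an estimated correlation, and exact permutation p = 0.0281, adjusted p = 0.173). Acta2 was at -0.46 ± 0.29 (adjusted p = 0.372). Among 11 matrix proteases and inhibitors, Plaur fell over all probe sets and 5 adjusted over the list alone, which adds Mmp2, Ctsk, Plat and Adamts1 (list difference -0.60, camera adjusted p = 3.78e-05, adjusted p = 0.583 with an estimated correlation, and exact permutation p = 0.013, adjusted p = 0.162). Mmp2 (-0.96 ± 0.253, adjusted p = 0.0535) passed over all probe sets with a stricter filter, an intensity trend, the mean of probe sets, both scalings and without ligated saline 4 (lowest adjusted p = 0.0167). Timp1 was at -0.60 ± 0.308 (adjusted p = 0.276). In the TGF-beta pathway Tgfbi rose by 0.52 ± 0.111 (adjusted p = 0.0349), Tgfbr1 and Skil fell adjusted over the list alone, and Tgfb1 was at 0.31 ± 0.193 (list difference -0.19, camera adjusted p = 0.0385, adjusted p = 0.667 with an estimated correlation, and exact permutation p = 0.26). The TGF-beta list lost its shift with a stricter filter, with the mean of probe sets and without sham 6, ligated saline 1, 3 or 5, or ligated ghrelin 2 or 5, and its difference was -0.105 without ligated saline 1 (adjusted p = 0.143).

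Among inflammatory genes, Ptgs2 was the only 1 of 24 cytokines, chemokines and NF-kB targets to pass, over all probe sets and adjusted over the list alone. It fell by 1.07 ± 0.246 (adjusted p = 0.0389), from a mean of 4.95 to 3.88, which lies below the filter level, so the size of the decrease is approximate (list difference -0.39, camera adjusted p = 0.00465, adjusted p = 0.667 with an estimated correlation, and exact permutation p = 0.0909). The list lost its shift with a stricter filter (adjusted p = 0.0792). Ccl2 was at -0.87 ± 0.307 (adjusted p = 0.121). Macrophage and Kupffer cell markers had 0 of 17 called (list difference -0.29, camera adjusted p = 0.00753, adjusted p = 0.667 with an estimated correlation, and exact permutation p = 0.106), and the shift was lost without ligated saline 2 or ligated ghrelin 2 or 3 (highest adjusted p = 0.0742). Members with low p were Itgax (-0.79 ± 0.238) and C1qb (-0.40 ± 0.165), neither of which passed. Neutrophil, lymphocyte, endothelial, MHC class II, interferon and acute phase lists did not pass by camera, with adjusted p between 0.0838 and 0.956. The MHC class II list had a mean of -0.19 and a median of -0.49, and passed without a filter, under both scalings and without sham 3 or 5 or ligated ghrelin 4 (lowest adjusted p = 0.0196). The lymphocyte list passed without a filter or ligated saline 3, the endothelial list without ligated ghrelin 3 and the interferon list without ligated ghrelin 5.

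Lists of lipid, protein and amino acid metabolism were higher with ghrelin by camera with its preset correlation and did not pass the other tests. In the lipogenesis list Srebf1 rose over all probe sets and 10 of 16 genes rose adjusted over the list alone, and the list mean was -0.26 ± 0.279 relative to sham with ghrelin and -0.72 ± 0.295 with saline (difference 0.46, camera adjusted p = 5.43e-05, adjusted p = 0.583 with an estimated correlation, and exact permutation p = 0.0325, adjusted p = 0.173). The triglyceride-forming enzyme Dgat1 was at 0.34 ± 0.0944 (adjusted p = 0.0609) and passed with a stricter filter, equal array medians and without ligated saline 2 or 4 (lowest adjusted p = 0.0385). Cholesterol synthesis and uptake (difference 0.31, camera adjusted p = 0.0074), hepatocyte secreted proteins and coagulation (0.13, adjusted p = 0.00815) and urea cycle and amino acid catabolism (0.25, adjusted p = 0.0278) each had 0 members called. For these 3 lists the adjusted p with an estimated correlation was 0.667, 0.667 and 0.672, and the exact permutation p was 0.199, 0.0693 and 0.459. Without ligated saline 1 none of the 3 shifted, with differences of 0.157 (adjusted p = 0.115), 0.094 (adjusted p = 0.0586) and 0.046 (adjusted p = 0.583). The cholesterol list also lost its shift without ligated ghrelin 2 (0.214, adjusted p = 0.0742), the secreted protein list after quantile normalization (adjusted p = 0.0783), and the urea cycle list with a stricter filter, both scalings, the mean of probe sets and without ligated ghrelin 2 (0.166) or 5 (0.148). Members with the lowest p were Dhcr7 (0.60 ± 0.196) and Fdps (0.44 ± 0.143), Proc (0.28 ± 0.085) and F10 (0.36 ± 0.11), and Prodh (0.65 ± 0.215) and Agxt (0.49 ± 0.174), none of which passed, except in some settings Proc and F10. In the growth hormone and IGF axis, which did not shift as a list (camera adjusted p = 0.497), Igfals (0.64 ± 0.146, adjusted p = 0.0389) and Igfbp4 (0.52 ± 0.118, adjusted p = 0.0382) rose and Jak2 (-0.49 ± 0.117, adjusted p = 0.043) fell, and among immediate early genes Egr2 fell by 1.329 (adjusted p = 0.0411). These 4 were chosen after their values were seen, and each lost the call under several alternatives.

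The remaining lists did not pass for ghrelin. Cholangiocyte markers differed by -0.03 with a median of 0.04 (camera adjusted p = 0.745) and members on both sides of 0, bile acid synthesis by 0.07 (adjusted p = 0.239), hepatobiliary transporters by 0.09 (adjusted p = 0.424), phase I drug metabolism by 0.18 (adjusted p = 0.0931), fatty acid oxidation by 0.09 (adjusted p = 0.282) and the cell cycle list by -0.20 (adjusted p = 0.0931). The cell cycle list passed without a filter (adjusted p = 0.0286), with equal array medians (adjusted p = 0.0158) and without ligated saline 2, 5 or 6 or ligated ghrelin 4, with a difference of -0.404 without ligated saline 5 (adjusted p = 0.000113). The drug metabolism list passed without ligated saline 4 or 6 or ligated ghrelin 1 or 3 (lowest adjusted p = 0.0156). Cyp7a1 (-0.14 ± 0.244), Cyp8b1 (-0.09 ± 0.61), Slc10a1 (0.17 ± 0.151), Abcb11 (0.17 ± 0.168), Abcc3 (0.18 ± 0.195), Krt7 (0.16 ± 0.36), Hmox1 (-0.38 ± 0.256), Igf1 (0.12 ± 0.0967), Ghr (0.28 ± 0.155) and Alb (0.01 ± 0.0525, at the top of the scale) did not pass (adjusted p between 0.319 and 0.95). Antioxidant, glucose metabolism, apoptosis, ER stress, housekeeping, erythroid, adipocyte and intestinal lists had camera adjusted p between 0.0931 and 0.75. Of these, the antioxidant and glucose metabolism lists passed without ligated saline 2 or ligated ghrelin 3, and the apoptosis list with a stricter filter (-0.247, adjusted p = 0.0233). Adjusted over their lists alone, Khk and Calr rose and Fabp4 fell, none of which passed over all probe sets. Immediate early genes did not shift as a list (camera adjusted p = 0.27).

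In all, 10 of 32 lists shifted by camera with its preset correlation (4 up and 6 down), 0 with an estimated correlation (lowest adjusted p = 0.583, with 2 lists at an unadjusted p under 0.05), and 0 by the exact permutation test (lowest adjusted p = 0.162, with 7 lists at an unadjusted p under 0.05). These 7 include lists that camera did not shift. They are the adipocyte (-0.40, exact permutation p = 0.00649, the lowest of all lists), apoptosis (-0.12, exact permutation p = 0.0152) and growth hormone and IGF lists (0.17, exact permutation p = 0.0433). The rest are the matrix, stellate cell, protease and lipogenesis lists. Of 100 splits of the 11 ligated arrays into groups of 5 and 6, 61 shifted at least 10 lists, so chance was not excluded for the number of lists.

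The comparison of ligated ghrelin with sham rats holds ligation and ghrelin together. Most matrix, bile duct and cell cycle genes were higher than in sham, and most genes of fatty acid oxidation and bile acid synthesis were lower. Col1a1 rose by 3.90 ± 0.303 (adjusted p = 4.05e-08), Col3a1 by 1.82 ± 0.145 and Krt19 by 5.06 ± 0.517, and Cyp2c11 fell by 7.37 ± 0.887 (n = 5 and 6). Loxl1 rose by 6.17 ± 0.312 and Mki67 by 4.11 ± 0.319. For genes called in the ghrelin comparison, Plaur lay below the filter level on all arrays of both groups, so no difference is given. Srebf1 was at -0.42 ± 0.18 (adjusted p = 0.0573) and Tgfbi at 0.00 ± 0.111 (adjusted p = 0.994).

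In this comparison 8534 probe sets passed (4776 higher and 3758 lower), with 56% higher on the deposited values, 43.9% after quantile normalization and 43.1% with array medians set equal. These scalings moved the median change of all kept probe sets by -0.12 each. Of the 32 lists, 21 shifted (12 up and 9 down), and 0 with an estimated correlation (lowest adjusted p = 0.251). Among matrix genes 25 of 27 rose, among cholangiocyte markers 12 of 14, and among cell cycle genes 30 of 31, while 20 of 21 fatty acid oxidation genes and 11 of 16 bile acid synthesis genes fell, with camera adjusted p between 1.41e-09 and 0.000122 and adjusted p between 0.251 and 0.343 with an estimated correlation. Of glucose metabolism genes 8 of 11 fell and 1 rose (camera adjusted p = 0.000609), and of phase I drug metabolism genes 17 of 26 fell and 1 rose (camera adjusted p = 3.7e-06), both with adjusted p = 0.251 with an estimated correlation. In the urea cycle list 13 of 26 fell (camera adjusted p = 0.000266, and adjusted p = 0.455 with an estimated correlation) and of secreted proteins 6 of 23 fell and 1 rose (camera adjusted p = 0.0182, and adjusted p = 0.507 with an estimated correlation). In lipogenesis 5 of 16 fell and 2 rose (camera adjusted p = 0.0459, and adjusted p = 0.533 with an estimated correlation), and in cholesterol synthesis 6 of 17 fell and 1 rose (camera adjusted p = 0.0246, and adjusted p = 0.6 with an estimated correlation). These last 2 lists did not pass the exact permutation test (adjusted p = 0.0816 each).

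Whether ghrelin moved the ligation response as a whole was asked with a score over genes chosen without regard to ghrelin. The 1997 genes that differed by at least 1 log2 unit between all 11 ligated arrays and sham (1464 higher and 533 lower) gave a mean shift of 2.07 ± 0.257 (SD, n = 6) with saline and 1.82 ± 0.186 (n = 5) with ghrelin. The difference of -0.25, which is -11.9% of the saline score, was within the spread between rats (exact two-sided permutation p = 0.136 over 462 splits, where the smallest possible p is 0.00216). With single arrays left out it ranged from -0.298 without ligated ghrelin 4 to -0.16 without ligated saline 1.

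Gene by gene, 77.2% of the 6301 genes called for ligation had a ghrelin difference of the opposite sign. Both comparisons use the ligated saline arrays, which can create opposite signs. With those 6 arrays divided between the comparisons, 3 for each, the share averaged 74.5% over 20 divisions (from 61.5 to 82.8), and in 100 simulations with no ghrelin effect it averaged 51.2% and ranged from 18.3 to 85.9, with 10 as high as observed. The covariance of the changes across genes was -0.173, against a simulated mean of -0.0268 (6 of 100 as low), a difference of -0.146, and the correlation across genes was -0.51 against -0.09 (15 of 100 as low). The simulations ranged widely. They kept the genes called on the real arrays and the observed ligation changes. Their average therefore cannot show opposite signs that arise when genes are called on the shared arrays. The 3 and 3 divisions also kept the genes called with all 6 saline arrays. Genes are not independent replicates, and opposite signs were not set apart from what spread between rats produces with these arrays shared.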

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

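The tests of RNA integrity, gene length, the male-biased genes and the clock genes were chosen after the data were seen, and the other divisions of the arrays were set beforehand. In 360 groups of arrays, 24 held an array far from the rest of its group, where chance gives about 1 in 20 groups, or 18. Of the 24, 6 are on ligated ghrelin 2, 4 on sham 1 and 3 on ligated saline 1.

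Among genes in sham rats, Acta2 was 2.92 on sham 2 (others 4.22 to 4.64), Alb 15.81 on sham 1 (15.88 to 15.92), and Amacr 13.04 on sham 5 (13.74 to 14.10). Klf6 was 7.67 on sham 3 (8.21 to 8.50), Krt7 4.78 on sham 4 (2.99 to 3.56), Msln 4.71 on sham 1 (2.36 to 2.94) and Vil1 3.40 on sham 1 (2.72 to 2.96). In ligated saline rats, Apoa4 was 12.49 on array 5 (10.55 to 11.25), Cyp4f4 9.42 on array 1 (10.34 to 10.52), Dhcr7 9.82 on array 1 (10.61 to 10.96) and Stac3 2.94 on array 6 (2.70 to 2.72). In ligated ghrelin rats, Col1a1 was 9.89 on array 3 (9.47 to 9.51), Itga5 6.47 on array 2 (6.85 to 6.96), Plaur 3.52 on array 3 (3.73 to 3.76) and Rgs5 7.45 on array 2 (7.69 to 7.77). Col1a1 had the same value, 9.471, on ligated ghrelin 1, 2 and 4 and on ligated saline 4. Its gap and its small spread with ghrelin therefore rest on tied values.

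Among list means relative to sham, matrix proteases and inhibitors were at -0.18 on sham 3 (others 0.02 to 0.06), cholangiocyte markers at 0.31 on sham 1 (-0.12 to 0.00) and hepatocyte secreted proteins at -0.081 on sham 6 (-0.01 to 0.03). Lipogenesis was at -0.16 on ligated saline 2 (-1.01 to -0.71) and the urea cycle list at -1.93 on ligated saline 1 (-0.94 to -0.50). On ligated ghrelin 2, cytokines and chemokines were at 0.92 (1.25 to 1.36), lymphocyte markers at -0.11 (0.23 to 0.28), neutrophil markers at 1.64 (2.27 to 2.51) and phase I drug metabolism at -0.70 (-1.33 to -1.17).

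The first pattern weighed is the 355 ghrelin calls, where called genes that were higher had a median genomic length of 10.8 kb, those lower 45.2 kb and all genes 23.8 kb. With and without the actin covariate, the ratio of the changes had a median of 0.94 and a lower quartile of 0.879. The calls fell to 44 as the median absolute change went from 0.55 to 0.52 and the median SE from 0.12 to 0.126. The actin value differed little between the groups (0.174, exact permutation p = 0.229), so adjusting for it could hardly move the changes. GAPDH (0.152, exact permutation p = 0.0541) was not used as a covariate, so RNA integrity as a source stays undecided. The slopes of a gene length trend of the arrays differed by -0.0926 (exact permutation p = 0.0346, an idea that came from the called genes). Such a trend as the whole source is argued against by a median ratio of 0.943 after its removal, with a lower quartile of 0.889. In a fit of genes with a known length, 370 were called before and 216 after the trend was removed, 199 of them in both, as the median absolute change went from 0.49 to 0.47 at the same median SE of 0.112. Calls close to the threshold may owe their side of it to RNA integrity or length, and an effect of ghrelin, which the design names, stays open.

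The second pattern is the fall of all 9 measured male-biased liver genes after ligation, by a list mean of -4.13 ± 0.907 (SD, n = 6, exact permutation p = 0.00216, the smallest these splits allow). Cyp2c11, Obp3 and Car3 are among them, and of 6 female-biased genes Cyp2c12 (4.58 ± 0.528) and Trim24 (2.44 ± 0.27) rose and Cyp2c7 fell by 0.648. Female rats in the ligated groups are argued against by the Y-linked gene Eif2s3y, whose lowest ligated value was 10.52 (sham 10.60 to 10.98), and by Xist, at most 2.65 on any array. A smaller share of hepatocytes as the whole source, which lowers all hepatocyte genes alike, is argued against by the 9 lists of hepatocyte genes that fell, the lowest of which had a mean of -1.32 ± 0.309, or 2.81 ± 0.658 above the male list (SD, n = 6), and the female list was 1.07 higher than in sham (exact permutation p = 0.00649). That gap rests mainly on Obp3 (-9.33), Car3 (-9.11) and Cyp2c11 (-7.77). The other male-biased genes changed by -2.26 to -1.06, so for them a smaller share stays open. The male list was drawn up after some of its genes were seen among the largest decreases and 3 of the 6 female-biased genes did not pass, so a loss of the male pattern was not tested on its own and stays open, and with ghrelin the male list differed by 0.45 (exact permutation p = 0.403).

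The third pattern is the fall of all 7 measured clock output genes after ligation, by a list mean of -2.82 ± 0.459 (SD, n = 6, exact permutation p = 0.00216), with Dbp at -4.62 ± 0.566 and Nr1d1 at -3.22 ± 0.492. Of the genes in antiphase to them, Bmal1 (2.66 ± 0.626), Npas2 (2.37 ± 0.566) and Clock (0.41 ± 0.172) rose and Nfil3 (0.40 ± 0.177, adjusted p = 0.0591) did not pass. A smaller share of hepatocytes as the whole source is argued against by the antiphase list, which was 1.46 higher (exact permutation p = 0.00216). Another time of day at sampling cannot be told apart from an effect of ligation, since the labels used give no time and 0 of 11 ligated arrays lay within the sham range of the antiphase minus output index (-1.71 to 1.84 in sham and 3.45 to 5.31 in ligated rats). With ghrelin the antiphase list was 0.33 higher (exact permutation p = 0.0281, without adjustment) and the output list differed by 0.07 (exact permutation p = 0.779).

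Chance as the source of the number of calls was tested with 100 divisions of the same arrays, the real one included. For the calls of ligation, 1 division reached 9823 (highest other 5207), for those of ghrelin 1 reached 355 (highest other 185) and for ligation with ghrelin 1 reached 8534 (highest other 6358). By the limit set beforehand this argues against chance for these counts, but 100 divisions, where the smallest share is 1 in 100, do not exclude it. The ghrelin count also moved with single arrays, to as few as 35. For the number of lists, 8 divisions reached the 21 of ligation (highest other 23) and 61 the 10 of ghrelin (highest other 18), so chance cannot be excluded for these counts by camera. The other divisions shifted a median of 13 and 11 lists, which may come from a structure of the samples or from correlated genes. For ligation, divisions with sham and ligated arrays in unequal shares also keep part of the ligation effect. Tested each on its own by exact permutation, 26 of 32 lists differed with ligation (lowest adjusted p = 0.00314), including all 21, and 0 with ghrelin (lowest adjusted p = 0.162). For ligation with ghrelin 2 divisions reached 21 lists, the real one and another that equalled it. Few divisions did so, a share under the limit set beforehand. Because another division equalled the real count, chance is not excluded for this count either.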

How the results depend on the processing

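The actin covariate, the length trend and the leave-outs of the RNA integrity controls were chosen after the data were seen. All 89 named ligation genes that passed kept direction and call in 2198 of 2198 gene-by-setting results. Of 388 such results for the 16 named ghrelin genes, 300 kept the call, 88 lost it and 0 changed direction. The actin covariate and the length trend are not among these results. Shifted lists kept their call in 458 of 483 results for ligation (21 of the 25 losses with the estimated correlation) and 197 of 230 for ghrelin. Of the results for named items that did not pass, 4 of 75 ligation genes, 7 of 249 ligation lists, 26 of 769 ghrelin genes and 25 of 502 ghrelin lists passed in the same direction elsewhere. A further 4 results for ligation lists, 13 for ghrelin genes and 22 for ghrelin lists changed sign without passing in either setting. Among list members chosen after their values were seen, 16 of 19 called for ligation and 0 of 4 called for ghrelin kept the call in all settings. For 44 that did not pass for ligation, 65 results passed in the same direction and 35 changed sign without passing, and for 23 for ghrelin 19 and 3 did so.

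Counts of called probe sets for ligation, ghrelin and ligation with ghrelin were 22230, 154 and 19914 without a filter, which tests more probe sets. They were 3338, 35 and 2753 with a change of at least 1 and 5338, 198 and 4077 with B above 0, both stricter by construction. The stricter filter gave 5144 for ligation and 4552 for ligation with ghrelin, from fewer probe sets. For ghrelin, quantile normalization gave 542, equal array medians 611, the 2 groups alone 118 and the actin covariate 44 (the cause was not tested). In a separate fit of genes with a known length, 370 were called for ghrelin, and 216 with the length trend removed. With the estimated correlation, camera shifted 0, 0 and 0 lists, with 4, 2 and 4 at an unadjusted p under 0.05, as the correlation widens the null. The opposite signs went from 77.16% to 74.55% with the saline arrays divided.

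Leaving out 1 array gave 9215 to 10037 calls for ligation, 35 to 653 for ghrelin and 7805 to 8606 for ligation with ghrelin. The ghrelin count was 196, 215, 338, 461, 198 and 221 without sham 1 to 6, 51, 381, 55, 653, 75 and 141 without ligated saline 1 to 6, and 97, 35, 122, 599 and 52 without ligated ghrelin 1 to 5. Shifted lists ranged from 21 to 22, 6 to 13 and 18 to 21, with 6 for ghrelin without ligated saline 1 or ligated ghrelin 2. The score difference ranged from -0.298 to -0.16 (exact permutation p 0.10 to 0.27).

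For ligation, 4 genes with values above 0 that did not pass changed sign and passed as lower in another setting. Smad6 was at -0.243 (adjusted p = 0.0123, highest 0.594 over its settings) and Stat5a at -0.331 (adjusted p = 0.00658, highest 0.99) after quantile normalization, and Fn1 at -0.182 with equal medians (adjusted p = 0.0357, highest 0.997). Prlr ranged from -1.105 without sham 5 (adjusted p = 0.0338, highest 0.989) to 0.501 without sham 3. The change of Fn1 is that of the scaling itself, which moves every probe set by -0.189. For Smad6, Stat5a and Prlr the cause was not tested. Intensities near the filter level limit what can be measured, and Tnf, Ghrl and Ghsr did not pass the filter.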

Other observations

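The tests of the shares of matrix, cholangiocyte and other lists were chosen after the result was seen. Male-biased genes of rat liver fell after ligation both within and outside the drug metabolism list. Outside it, Sult1e1 changed by -2.26 ± 0.445 (log2 change ± SE, n = 6 and 6, limma adjusted p = 0.000334) and Slco1a1, a transporter, by -1.87 ± 0.172. Within it, Cyp3a2 changed by -2.21 ± 0.483 and Cyp2a2 by -1.74 ± 0.207. The core clock repressors Per2 (-2.43 ± 0.368) and Per3 (-2.93 ± 0.27) and the PAR-domain factors Tef (-2.40 ± 0.26) and Hlf (-2.94 ± 0.289) fell as well. None of these genes passed for ghrelin by limma (adjusted p between 0.146 and 0.954).

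The bioB hybridization spike, the lowest in concentration of the controls added to each sample, gave intensities of 294 to 418 on the sham arrays and 116 to 274 on the ligated arrays. These ranges do not overlap. A technical difference between sham and ligated arrays at low intensity can therefore not be told apart from ligation, which limits the ligation changes of weakly expressed genes.

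A hypothesis is that ghrelin lowered the ligation response of matrix genes more than that of bile duct genes. As a share of the mean ligation change, the matrix list differed with ghrelin by -25.3 percentage points (exact permutation p = 0.0325) and the cholangiocyte list by -0.754 (p = 0.929 in the same exact test). The difference of the shares was -24.5 percentage points (exact permutation p = 0.0195). The pair was picked because its lists differed on these arrays. Over all 12 lists that ligation raised, picked without regard to ghrelin, the shares varied between lists by 11.1 percentage points (SD), which other divisions of the ligated arrays often matched (exact permutation p = 0.461). A response smaller in equal proportion therefore stays open and cannot be told apart from a lowering of matrix genes in particular.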
